A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

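Gene expression was measured in S. cerevisiae CENPK 113-7D with Affymetrix arrays, 3 in log phase and 3 each on days 2, 6 and 10. Per the labels these are days in stationary phase, while the series description counts days in culture, and which holds is not settled here. Total RNA came from frozen cell pellets and was labelled with biotin, per the labels' protocols. The values are the authors' deposited probe set summaries, made with PLIER per the submitters' processing notes. PLIER is a model that combines the probes of a probe set. Its version, the background correction and the normalization between arrays are not given in the sources used here. The deposited values were taken as log2 values because of their range, with a lowest value of 5.11 and a highest of 13.79. No value lies near 0, so the scale has a floor, and differences of dim genes are compressed towards it and understate the change. The median over all genes per array ran from 7.80 to 7.89.

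The table held 10928 probe sets. Of these 213 were controls, 7244 had 1 gene in the platform annotation, 1 had several and 3470 had none there. Genes were matched through their gene ID to a RefSeq table of the S288C reference strain, which updated 12 symbols and is not the strain studied, so a probe can differ from the strain's sequence. This left 5498 probe sets for 5449 S. cerevisiae genes. For the 47 genes with several probe sets the probe set with the highest mean over all 12 arrays stood for the gene. The 1746 probe sets of genes of another yeast species served as background: the 95th percentile of their means was 5.82, and 188 S. cerevisiae genes had a mean below it. Where a group's mean lay below the mean 95th percentile of these probe sets on its own arrays (5.79 on day 6 to 5.84 in log phase), a fold is given as a lower bound. No genome was used and no coordinates are given.

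Samples were grouped by the growth phase in the labels. A linear model with a coefficient for each time was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom, 12.9 with the prior and a prior standard deviation of 0.0867. Moderated F tests compared the 4 times and days 2, 6 and 10, and 6 contrasts compared the times in pairs. P-values were adjusted by the Benjamini-Hochberg method within each test, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from limma. Fixed gene lists, 41 in number, were tested with camera at a preset correlation of 0.01 and adjusted over the 40 lists tested, and again with an estimated correlation. The list of mitochondrially encoded genes had 0 measured members. The design, the lists, the naming rule and all alternatives but those named below as added were fixed before the data were examined.

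Genes are named by a rule: in each contrast the 5 highest and 5 lowest called genes whose arrays do not overlap between the groups, up to 4 called members of a described list with the largest change, any of 49 sentinel genes, of which 48 were measured, and the 10 genes with the highest F among days 2, 6 and 10. The fit was tested on simulated data for day 2 against log phase with 200 of 5449 genes changed. It recovered 42% of 50 genes changed by 0.25 on the log2 scale, 90% at 0.5, 98% at 1 and 100% at 2, with 10 false calls. The simulated noise was independent between genes, and the data called 4387 genes in this comparison, so these rates need not hold there.

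The alternatives were an offset of 16 on the linear scale, quantile normalization, median centring, centring on 27 hybridisation control probe sets, a filter on dim genes, all probe sets tested separately, the mean of a gene's probe sets, a prior with trend and robust settings, the 6 arrays of each contrast alone, the replicate number as a block, array weights, each array left out in turn and a 2-fold minimum. The iteration for array weights stopped before it reached its convergence tolerance. After the data were seen, centring on the 18 hybridisation control probe sets other than bioB and a covariate were added. The covariate was the mean 3' minus 5' signal of 8 control genes, and it was also used in the tests of the lists. All 12 deposited columns were used.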

Results

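The series followed gene expression in yeast from growth into stationary phase, the setting in which chronological ageing, the survival of cells that have stopped dividing, is studied. The laboratory strain CENPK 113-7D was grown in synthetic medium with 2% glucose. RNA was hybridised to Affymetrix arrays from 4 times: logarithmic growth (log phase) and days 2, 6 and 10. The sample labels count these days in stationary phase and the series description counts them in culture, so their starting point is not settled. Each time had 3 arrays, 12 in all, and 5449 S. cerevisiae genes were measured on each. Per array, between 5137 and 5259 genes lay above the 95th percentile of the probe sets of another yeast species that are printed on the same array. The number of arrays limits the precision of every value. The labels do not say whether the 3 arrays of a time came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component held 66.8% of the variance and separated log phase from the other times, and the second held 20%.

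All differences are on the log2 scale of the deposited values, given with the standard error of the limma fit and n = 3 arrays per time. They describe a gene relative to the other genes of its array. When arrays were instead centred on the bacterial and phage hybridisation controls, the median of all genes moved by -0.42 for day 2, -1.19 for day 6 and -0.97 for day 10 against log phase. It moved by -0.77 for day 6 against day 2, by 0.22 for day 10 against day 6 and by -0.55 for day 10 against day 2. That scaling moves every gene and every list median of a comparison by this same amount. Hybridisation controls do not measure the RNA per cell, and the normalization between arrays is not given. The shifts are thus no measure of how many transcripts rose or fell per cell. One of these controls, bioB, was low against another, bioC, on the log phase arrays. Without bioB, an alternative chosen after the data were seen, the shifts were -0.05, -0.86 and -0.64 for days 2, 6 and 10 against log phase. They were then -0.81 for day 6 against day 2, 0.21 for day 10 against day 6 and -0.59 for day 10 against day 2. A described list whose direction turned under either centring has both values given beside it. Of the 40 gene lists tested, the preset correlation of camera called between 18 and 26 in each comparison. With an estimated correlation camera called 0 lists in each of the 6 comparisons, and between 4 and 9 lists had an unadjusted p under 0.05.

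**Figure D1:**
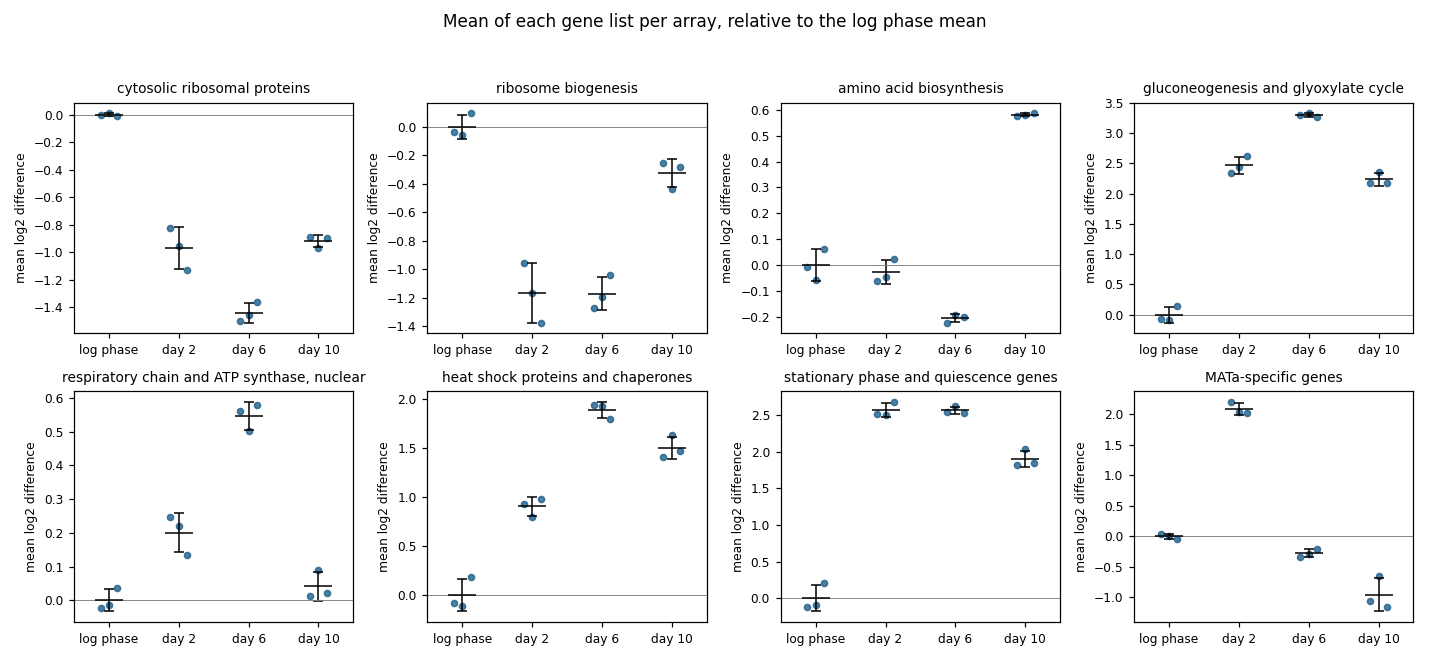
Mean log2 difference from the log phase mean for 8 gene lists on each of the 12 arrays, against time; points are arrays, and bars are the mean and SD of 3 arrays. The ribosome biogenesis list lay between -1.37 and -0.95 on day 2 and between -0.44 and -0.25 on day 10, and the MATa-specific list was highest on day 2, between 2.02 and 2.21.

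The first comparison asked what changed between growth and day 2. All 127 cytosolic ribosomal protein genes fell (median -0.88). RPS28B was at -2.52 ± 0.14 and RPL22B at -2.29 ± 0.18. Of 91 ribosome biogenesis genes 89 fell and 1 rose (median -1.10), among them UTP6 at -2.11 ± 0.09 and MRT4 at -2.03 ± 0.15. Of 65 mitochondrial ribosomal protein genes 62 fell, or 63 adjusted over the list alone, with MRPL15 at -1.62 ± 0.09. The adjusted p of these 3 lists was 3.76e-18, 3.23e-14 and 1.82e-11, and the adjusted p = 0.309, 0.369 and 0.309 with an estimated correlation. Subunits of RNA polymerases I and III were among the lowest genes of the comparison, RPA12 at -2.77 ± 0.12 and RPC11 at -2.75 ± 0.15. The others among the 5 lowest were UTR2, a cell wall transglycosylase, at -3.05 ± 0.07, the cytochrome CYB5 at -2.92 ± 0.11 and SER2 of serine synthesis at -2.71 ± 0.07.

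All 22 genes of gluconeogenesis and the glyoxylate cycle rose on day 2 (median 2.46, adjusted p = 8.67e-09), including the lactate transporter JEN1 at 4.44 ± 0.08, malate synthase MLS1 at 4.04 ± 0.22 and isocitrate lyase ICL1 at 3.94 ± 0.17. Of 21 TCA cycle genes 20 rose (median 0.94, adjusted p = 1.32e-05), with citrate synthase CIT1 at 2.66 ± 0.07. Of 21 genes of peroxisomal beta-oxidation 20 rose and 1 fell (median 1.16, adjusted p = 1.70e-06): POT1 was at least 9.88-fold higher, against a log phase level below background, and FOX2 rose by 1.97 ± 0.07. For all 3 lists the adjusted p = 0.175 with an estimated correlation. Trehalose and glycogen genes rose in 19 of 21 cases and fell in 1 (median 1.89, adjusted p = 5.57e-07; adjusted p = 0.309 with an estimated correlation), led by the branching enzyme GLC3 at 4.24 ± 0.16 and glycogen phosphorylase GPH1 at 3.78 ± 0.27. All 36 stationary phase genes rose (median 2.57, adjusted p = 5.84e-13; adjusted p = 0.175 with an estimated correlation): FMP45 was at least 20-fold higher, and SPG1 rose by 3.62 ± 0.16. Heat shock and chaperone genes rose in 20 of 29 cases and fell in 5 (median 0.82, and 0.40 centred on the hybridisation controls; adjusted p = 0.00545; adjusted p = 0.458 with an estimated correlation), with the small heat shock protein HSP26 at 3.20 ± 0.28. Antioxidant genes rose in 24 of 34 cases and fell in 6 (median 0.42, -0.00 centred on those controls and 0.37 without bioB; adjusted p = 0.0101; adjusted p = 0.369 with an estimated correlation), with the catalase CTT1 at 3.11 ± 0.20. Vacuolar hydrolases rose in 11 of 12 cases (median 1.23, adjusted p = 4.05e-05; adjusted p = 0.175 with an estimated correlation). AMS1 was at 3.12 ± 0.06 and PRB1 at 3.03 ± 0.09.

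Glycolytic genes went both ways, 7 of 16 higher and 5 lower (median 0.03, -0.39 centred on the hybridisation controls and -0.02 without bioB; adjusted p = 0.286). The glucose-phosphorylating enzymes HXK1 and GLK1 rose by 4.13 ± 0.19 and 3.22 ± 0.14, and enolase ENO2 was at -0.97 ± 0.11. Of 12 hexose transport genes 9 rose and none fell (median 0.82, adjusted p = 0.00154; adjusted p = 0.175 with an estimated correlation), HXT7 by 3.31 ± 0.14 and HXT5 by 3.09 ± 0.15. Of 22 genes of the iron regulon 19 rose and 1 fell (median 1.25, adjusted p = 4.72e-05; adjusted p = 0.309 with an estimated correlation). FIT3 was at 3.43 ± 0.10 and ARN1 at 2.86 ± 0.15. DNA replication genes fell in 28 of 40 cases and rose in 5, or 6 adjusted over the list alone (median -0.35, adjusted p = 0.00619; adjusted p = 0.404 with an estimated correlation). RFC5 was at -1.17 ± 0.08. The histone gene HTB2 was at -1.46 ± 0.06. Among regulators of lifespan the kinase gene RIM15 rose by 0.74 ± 0.05 and the transcription factor gene GIS1 by 1.51 ± 0.06, SIR2 fell by 0.25 ± 0.06, and TOR1 stood at -0.01 ± 0.05 and was not called. Centred on the hybridisation controls RIM15 was at 0.32 and not called and TOR1 was at -0.43 and called, but without bioB RIM15 was called at 0.70 and TOR1 was not called at -0.06. SIR2 was not called without bioB among those controls (-0.30) or with the RNA integrity signal of 8 control genes, 3' minus 5', as a covariate (-0.20).

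All 7 MATa-specific genes, of mating, rose on day 2 (median 2.34, adjusted p = 0.000788; adjusted p = 0.309 with an estimated correlation), with the agglutinin subunit AGA2 at 2.66 ± 0.12 and the pheromone protease BAR1 at 2.47 ± 0.10. Of 10 haploid-specific genes 9 rose and none fell (median 1.07, adjusted p = 0.000943; adjusted p = 0.175 with an estimated correlation), among them AGA1 at 3.80 ± 0.11 and FUS1 at 2.53 ± 0.10. Of the 4 MATalpha-specific genes, the markers of the other mating type, 3 rose: MF(ALPHA)1, which encodes alpha-factor, by 4.47 ± 0.13, SAG1 by 1.50 ± 0.09 and STE3 by 0.75 ± 0.06; centred on the hybridisation controls STE3 was at 0.33 and not called, and without bioB it was called at 0.70. That list was not called (adjusted p = 0.0651; adjusted p = 0.262 with an estimated correlation), but it was with the 3' minus 5' covariate (adjusted p = 0.0287 at the preset correlation). The highest genes of the comparison were THI4 of thiazole synthesis at 5.97 ± 0.08, 62.6-fold, and THI13 of pyrimidine synthesis for thiamine at 5.14 ± 0.07.

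In total 4387 of 5449 genes were called between day 2 and log phase, 2127 higher and 2260 lower, and 665 and 585 of these by at least 2-fold. Centred on the hybridisation controls the split was 903 higher and 3037 lower, and without bioB it was 1481 and 1804. The 3 arrays of a time did not overlap for 82.6% of genes, where chance gives 10%. The 1746 probe sets of another yeast species were also tested, by themselves. Against log phase 101, 247 and 182 of them were called on days 2, 6 and 10, and 0 by at least 2-fold. Between the later days 20 (day 6 against day 2), 12 (day 10 against day 6) and 2 (day 10 against day 2) were called. Small shifts against log phase thus passed the threshold in probe sets of another species, and their cause was not tested. Here and in the comparisons that follow, for lists with no other count given, the count adjusted over the list alone was that over all genes. The log phase arrays also differed from the others in a control: bioB minus bioC was -2.17 ± 0.08 (SD, n = 3) there and -0.79 ± 0.04 on day 2. A hybridisation batch behind this would enter every comparison with log phase and could not be told apart from growth phase. The 3' minus 5' signal of 8 control genes, a sign of RNA integrity, was 1.25 ± 0.07 in log phase and 0.86 ± 0.24 on day 2.

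**Figure D2:**
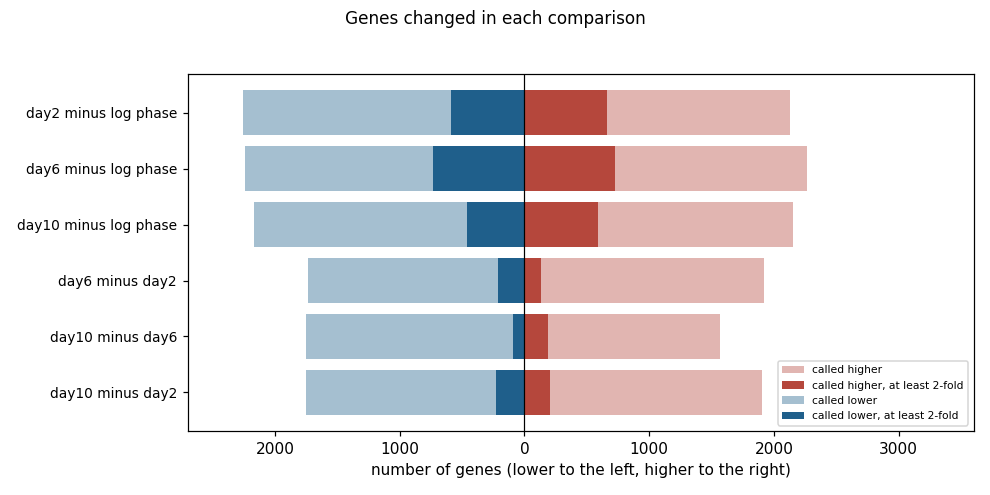
Number of genes called in each of the 6 comparisons, lower to the left and higher to the right, with those of at least 2-fold in the darker colour. The comparisons with log phase called between 4321 and 4505 genes, and those among days 2, 6 and 10 between 3319 and 3659.

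By day 6 all 22 gluconeogenesis and glyoxylate genes were higher than in log phase (median 3.39, adjusted p = 2.40e-09; adjusted p = 0.283 with an estimated correlation), with MLS1 at 5.63 ± 0.22, ICL1 at 5.06 ± 0.17 and PCK1, the first committed enzyme of gluconeogenesis, at 4.95 ± 0.21. Heat shock and chaperone genes were higher in 25 of 29 cases and lower in 2 (median 1.90, adjusted p = 3.06e-06; adjusted p = 0.307 with an estimated correlation), with HSP26 at 4.45 ± 0.28 and the Hsp70 gene SSA3 at 4.28 ± 0.12. All 36 stationary phase genes were higher (median 2.31, adjusted p = 3.15e-11; adjusted p = 0.283 with an estimated correlation), SIP18 by 5.69 ± 0.14 and GRE1 by 4.96 ± 0.14. Of 34 autophagy genes 29 were higher and 2 lower (median 1.07, -0.12 centred on the hybridisation controls and 0.21 without bioB; adjusted p = 1.67e-06; adjusted p = 0.307 with an estimated correlation). ATG8 was at 2.73 ± 0.09. HXT5, a hexose transporter of slow-growing cells, was at 5.46 ± 0.15 while HXT4 was at -3.64 ± 0.19 and HXT3 at -2.90 ± 0.09. THI4 was at 5.33 ± 0.08.

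Cytosolic ribosomal protein genes were lower in 126 of 127 cases on day 6, and in 127 adjusted over the list alone (median -1.40, adjusted p = 3.87e-23; adjusted p = 0.307 with an estimated correlation). RPS28B was at -3.23 ± 0.14 and RPL9A at -3.15 ± 0.11, and the other genes among the 5 lowest included UTR2 at -3.48 ± 0.07 and FUR1 of uracil salvage at -3.17 ± 0.09. Cyclin and G1/S genes were lower in 14 of 22 cases and higher in 4 (median -0.44, adjusted p = 0.0313; adjusted p = 0.47 with an estimated correlation; with the 3' minus 5' covariate -0.31 and adjusted p = 0.104), with the mitotic cyclin CLB1 at -2.43 ± 0.13, and the histone gene HTB2 was at -1.92 ± 0.06. TOR1 was at 0.15 ± 0.05, and SIR2 at -0.07 ± 0.06 was not called. The call of TOR1 was lost with quantile normalization (0.08), median centring (0.10), the 3' minus 5' covariate (0.09), without log phase replicate 2 (0.13) and without day 6 replicate 1 (0.13), and it turned to -1.04 centred on the hybridisation controls, where SIR2 was called at -1.26. In total 4505 genes were called, 2266 higher and 2239 lower, and 356 higher and 4555 lower centred on those controls. Without bioB 542 were higher and 3993 lower. The 3' minus 5' signal of the control genes was 1.65 ± 0.05 on day 6 and 1.25 ± 0.07 in log phase (SD, n = 3), and bioB minus bioC was -0.88 ± 0.02 on day 6. The control genes did not move alike. From log phase to day 6 the signal rose for ACT1 (1.18 to 2.33), WBP1 (1.81 to 2.64), EAF5, SPT15 and URA3. It was 0.55 and 0.61 for RIP1 and 2.26 and 2.22 for SRB4, and it fell for TDH1 (1.09 to 0.89).

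On day 10 amino acid biosynthesis genes were higher than in log phase in 27 of 43 cases and lower in 6 (median 0.54, -0.42 centred on the hybridisation controls and -0.10 without bioB; adjusted p = 0.000971; adjusted p = 0.36 with an estimated correlation), with CPA1 at 2.64 ± 0.09 and ARG1 at 2.04 ± 0.18 of arginine synthesis. Targets of nitrogen catabolite repression were higher in 22 of 28 cases and lower in 1 (median 0.75, -0.22 centred on those controls and 0.11 without bioB; adjusted p = 9.68e-05; adjusted p = 0.39 with an estimated correlation), with proline oxidase PUT1 at 3.25 ± 0.16 and the permease AGP1 at 2.38 ± 0.09. The sulfate transporter SUL1 was at least 14.9-fold higher, and the phosphate transporter PHO84 was at 4.83 ± 0.15. The highest genes also included THI4 at 5.20 ± 0.08, NCA3 at 5.19 ± 0.11, the cell wall protein PIR3 at 5.03 ± 0.11 and YMR244W at 4.48 ± 0.15.

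Ribosomal protein genes were still lower on day 10 than in log phase, 121 of 127, and 2 more adjusted over the list alone (median -0.83, adjusted p = 1.88e-18; adjusted p = 0.373 with an estimated correlation). Of the 91 ribosome biogenesis genes 51 were lower and 8 higher (median -0.33, adjusted p = 0.00387; adjusted p = 0.669 with an estimated correlation). DNA replication genes were lower in 23 of 40 cases and higher in 6 (median -0.34, adjusted p = 0.00602; adjusted p = 0.429 with an estimated correlation). POL30 was at -1.94 ± 0.12. CLB1 was at -2.34 ± 0.13, HTB2 at -2.05 ± 0.06 and the pheromone receptor gene STE2 at -1.85 ± 0.09. The lowest genes were ZPS1, a zinc-responsive gene, at -3.93 ± 0.24, HXT3 at -3.20 ± 0.09, UTR2 at -2.86 ± 0.07, AIM20 at -2.67 ± 0.08 and CYB5 at -2.63 ± 0.11. In total 4321 genes were called, 2151 higher and 2170 lower, and 381 higher and 4424 lower centred on the hybridisation controls. Without bioB 590 were higher and 3674 lower.

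The next comparisons asked what changed during the stationary days. The moderated F test called 5204 genes over the 4 times and 4631 among days 2, 6 and 10. The highest F among the stationary days belonged to THI13, whose level was 11.75 ± 0.11 on day 2, 8.68 ± 0.10 on day 6 and 7.96 ± 0.07 on day 10 (SD, n = 3). The next were HXT3, STE2, ALD5, TIP1, BAR1, FUS3, MF(ALPHA)1, AGA1 and STD1, and 5 of these 10 genes belong to the mating lists.

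**Figure D3:**
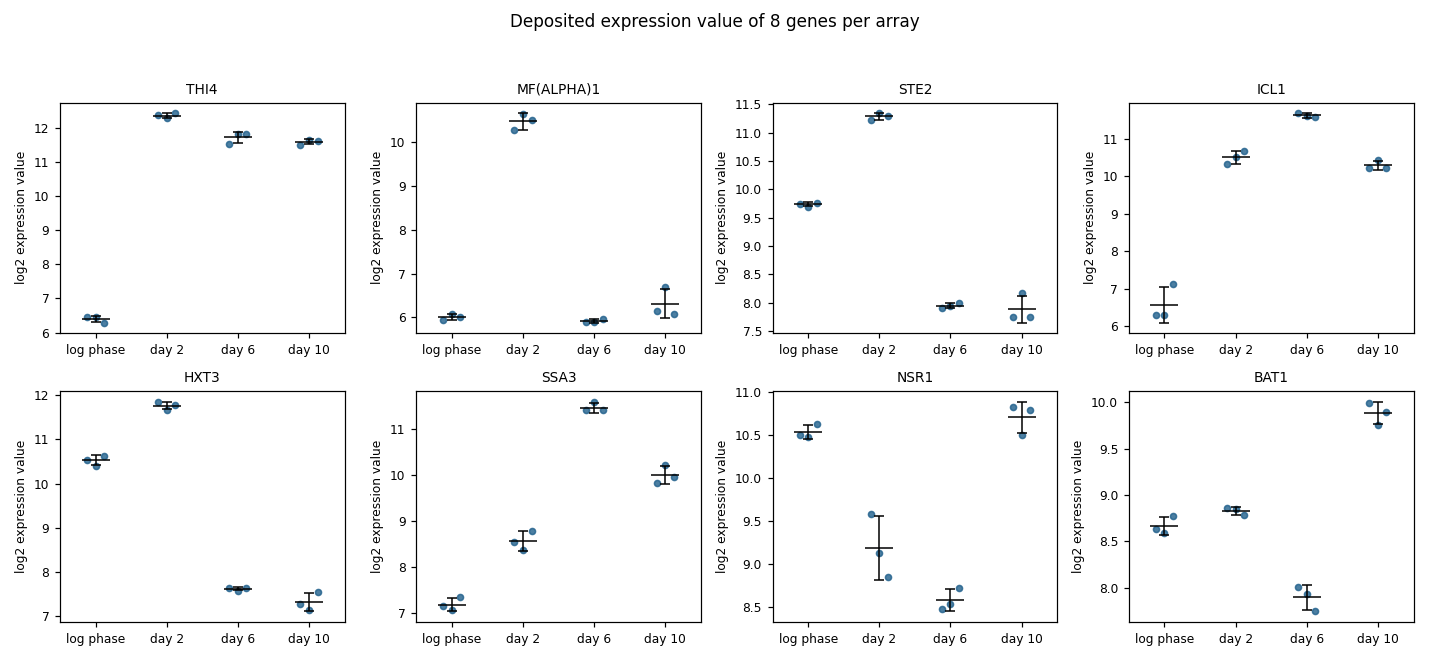
Deposited log2 expression value of 8 genes on each array, against time; points are arrays, and bars are the mean and SD of 3 arrays, with a separate axis range in each panel. MF(ALPHA)1 was at 10.48 on day 2 and at 5.92 on day 6, and NSR1 rose from 8.58 on day 6 to 10.71 on day 10.

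From day 2 to day 6 all 7 MATa-specific genes fell (median -2.11, adjusted p = 1.07e-05; adjusted p = 0.388 with an estimated correlation), with STE2 at -3.33 ± 0.09, BAR1 at -3.25 ± 0.10 and AGA2 at -2.87 ± 0.12. Of 10 haploid-specific genes 9 fell and none rose (median -1.69, adjusted p = 2.41e-05; adjusted p = 0.143 with an estimated correlation), with AGA1 at -3.06 ± 0.11, the kinase FUS3 at -2.13 ± 0.06 and FAR1 at -2.08 ± 0.13. Of the 4 MATalpha-specific genes 3 fell and the list was not called (adjusted p = 0.0523; adjusted p = 0.388 with an estimated correlation), but it was with the 3' minus 5' covariate (adjusted p = 0.0106 at the preset correlation). Among all genes MF(ALPHA)1 had the largest fall, -4.56 ± 0.13. It was followed by TIP1 at -4.30 ± 0.11, HXT3 at -4.14 ± 0.09, HXT4 at -3.89 ± 0.19 and the pyruvate decarboxylase gene PDC5 at -3.68 ± 0.14.

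Heat shock and chaperone genes rose in 25 of 29 cases from day 2 to day 6 and fell in 3 (median 1.02, and 0.25 centred on the hybridisation controls; adjusted p = 1.28e-06; adjusted p = 0.437 with an estimated correlation). SSA3 rose by 2.90 ± 0.12, HSP30 by 2.62 ± 0.15 and the Hsp90 co-chaperones CPR6 and STI1 by 1.84 ± 0.11 and 1.66 ± 0.10. Gluconeogenesis and glyoxylate genes rose in 17 of 22 cases and fell in 2 (median 0.87, 0.10 centred on those controls and 1.54 with the 3' minus 5' covariate; adjusted p = 0.000224; adjusted p = 0.437 with an estimated correlation). PCK1 was at 2.11 ± 0.21 and MLS1 at 1.59 ± 0.22. Respiratory chain genes rose in 25 of 37 cases and fell in 7 (median 0.42, -0.35 centred on the hybridisation controls and -0.39 without bioB; adjusted p = 0.00106; adjusted p = 0.437 with an estimated correlation). COX7 was at 1.19 ± 0.10. Mitochondrial ribosomal protein genes rose in 51 of 65 cases and none fell (median 0.37, -0.39 centred on those controls and -0.43 without bioB; adjusted p = 7.02e-08; adjusted p = 0.437 with an estimated correlation). MRPL33 was at 1.34 ± 0.10. The highest genes also included SPS100, named for sporulation, at 2.96 ± 0.16, the copper transporter CTR3 at 2.81 ± 0.17 and CIS1 at 2.50 ± 0.14. HXT5 rose by 2.37 ± 0.15.

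Cytosolic ribosomal protein genes fell in 96 of 127 cases over the same days and rose in 6 (median -0.51, and -0.84 with the 3' minus 5' covariate; adjusted p = 1.11e-12; adjusted p = 0.444 with an estimated correlation). RPL9A was at -1.46 ± 0.11 and RPS8B at -1.44 ± 0.11. Translation factor genes fell in 24 of 35 cases and rose in 1 (median -0.39, and -0.65 with the covariate; adjusted p = 3.89e-05; adjusted p = 0.437 with an estimated correlation). TIF4631 was at -1.08 ± 0.09 and PAB1 at -1.04 ± 0.08. All 10 fatty acid synthesis genes fell (median -0.87, adjusted p = 3.31e-05; adjusted p = 0.143 with an estimated correlation). FAA4 was at -1.52 ± 0.11 and FAS1 at -1.22 ± 0.07. Ergosterol genes fell in 16 of 25 cases and rose in 3 (median -0.48, adjusted p = 0.00187; adjusted p = 0.444 with an estimated correlation). ERG20 was at -1.18 ± 0.09. With the covariate that list had a median of -0.20 and was not called (adjusted p = 0.208). Glycolytic genes fell in 10 of 16 cases and none rose (median -0.51, adjusted p = 0.00114; adjusted p = 0.477 with an estimated correlation). HXK1 was at -1.97 ± 0.19 and HXK2 at -1.26 ± 0.11. With the covariate the glycolytic list had a median of -0.13 and was not called either (adjusted p = 0.586). The G1 cyclin CLN1 was at -1.16 ± 0.11 and CLB1 at -1.53 ± 0.13, while TDH3 at -0.05 ± 0.08 and ACT1 at -0.11 ± 0.07 were not called; centred on the hybridisation controls these were called at -0.82 and -0.87.

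In total 3659 genes were called between day 6 and day 2, 1920 higher and 1739 lower, and 102 higher and 4571 lower centred on the hybridisation controls. Without bioB 90 were higher and 4641 lower. The 3' minus 5' signal of the control genes was 0.86 ± 0.24 on day 2 and 1.65 ± 0.05 on day 6 (SD, n = 3). With that signal as a covariate, chosen after the data were seen, 1636 genes were called, of which 1382 had been called in the same direction without it; MLS1 (1.57), COX7 (0.47) and CLN1 (-0.72) were then not called.

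**Figure D4:**
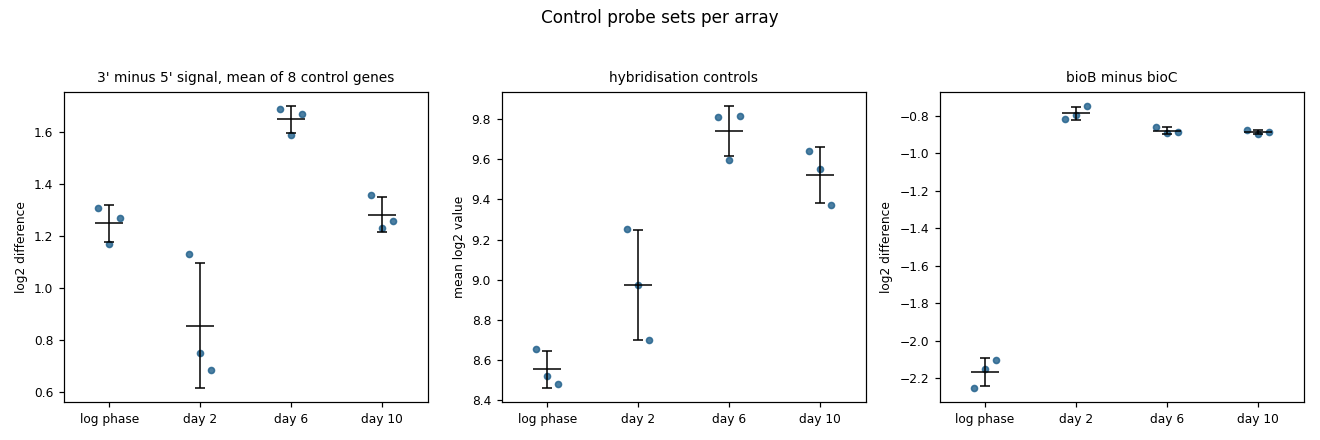
Control probe sets on each array, against time: the mean 3' minus 5' log2 signal of 8 control genes, the mean log2 value of the hybridisation controls, and bioB minus bioC; points are arrays, and bars are the mean and SD of 3 arrays. The 3' minus 5' signal was highest on day 6, at 1.65, and bioB minus bioC was lowest in log phase, at -2.17.

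From day 6 to day 10, of 91 ribosome biogenesis genes 86 rose and 1 fell, and 87 rose adjusted over the list alone (median 0.84, adjusted p = 5.02e-21; adjusted p = 0.451 with an estimated correlation), with the nucleolar proteins NSR1 at 2.12 ± 0.15 and NOP1 at 1.86 ± 0.10 and the helicase HAS1 at 1.72 ± 0.12. Cytosolic ribosomal protein genes rose in 101 of 127 cases and fell in 1, and 104 rose adjusted over the list alone (median 0.49, adjusted p = 6.67e-19; adjusted p = 0.451 with an estimated correlation). RPL9A was at 1.81 ± 0.11 and RPL5 at 1.41 ± 0.07. Translation factor genes rose in 32 of 35 cases and fell in 2 (median 0.66, adjusted p = 8.21e-11; adjusted p = 0.423 with an estimated correlation). YEF3 was at 1.32 ± 0.09. Genes of aminoacyl-tRNA synthetases rose in 17 of 18 cases and none fell (median 0.69, adjusted p = 6.39e-08; adjusted p = 0.444 with an estimated correlation). DED81 was at 0.95 ± 0.08. Amino acid biosynthesis genes rose in 34 of 43 cases and fell in 3, and 36 rose adjusted over the list alone (median 0.84, adjusted p = 2.12e-12; adjusted p = 0.156 with an estimated correlation), with HOM2 at 2.02 ± 0.10, BAT1 at 1.98 ± 0.08 and ARO4 at 1.78 ± 0.08.

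The highest single genes from day 6 to day 10 were ANS1 at 3.61 ± 0.27, YMR244W at 2.71 ± 0.15, methionine synthase MET6 at 2.28 ± 0.11, PHO84 at 2.21 ± 0.15 and the aldehyde dehydrogenase ALD5 at 2.20 ± 0.07. The arginase gene CAR1 rose by 2.14 ± 0.17. Cell wall genes rose in 17 of 24 cases and none fell, and 18 rose adjusted over the list alone (median 0.36, adjusted p = 3.70e-05; adjusted p = 0.444 with an estimated correlation). PIR1 was at 1.84 ± 0.17 and CIS3 at 1.57 ± 0.07.

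Gluconeogenesis and glyoxylate genes fell in 20 of 22 cases from day 6 to day 10 and none rose (median -1.12, adjusted p = 1.64e-07; adjusted p = 0.423 with an estimated correlation), with the carnitine acetyltransferases YAT1 at -2.28 ± 0.09 and YAT2 at -2.11 ± 0.11 and MLS1 at -1.70 ± 0.22. Respiratory chain genes fell in 31 of 37 cases and none rose (median -0.52, adjusted p = 8.59e-08; adjusted p = 0.327 with an estimated correlation). NDE2 was at -1.78 ± 0.12. TCA cycle genes fell in 17 of 21 cases and rose in 2, and 18 fell adjusted over the list alone (median -0.41, adjusted p = 0.000373; adjusted p = 0.444 with an estimated correlation). CIT3 was at -1.44 ± 0.11. Mitochondrial ribosomal protein genes fell in 45 of 65 cases and rose in 1, and 46 fell adjusted over the list alone (median -0.28, adjusted p = 3.96e-05; adjusted p = 0.551 with an estimated correlation). MRPL33 was at -0.76 ± 0.10. Trehalose and glycogen genes fell in 17 of 21 cases and none rose (median -0.62, adjusted p = 1.39e-05; adjusted p = 0.451 with an estimated correlation). PGM2 was at -1.37 ± 0.13. Stationary phase genes fell in 24 of 36 cases and rose in 5 (median -0.67, adjusted p = 9.75e-05; adjusted p = 0.451 with an estimated correlation), with FMP16 at -1.87 ± 0.18, SIP18 at -1.76 ± 0.14 and GRE1 at -1.54 ± 0.14. Heat shock and chaperone genes fell in 22 of 29 cases and rose in 2 (median -0.48, adjusted p = 0.00249; adjusted p = 0.551 with an estimated correlation). SSA3 was at -1.47 ± 0.12. The antioxidant genes CTT1 and SOD2 were at -1.48 ± 0.20 and -1.28 ± 0.09. ZPS1 at -3.24 ± 0.24 and CTR3 at -2.34 ± 0.17 were the lowest genes.

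Cyclin and G1/S genes rose in 2 of 22 cases from day 6 to day 10 and fell in 5 (adjusted p = 0.905). DNA replication genes rose in 8 of 40 and fell in 15 (median -0.10, 0.12 centred on the hybridisation controls and 0.11 without bioB; adjusted p = 0.121), and histone genes rose in 2 of 9 and fell in 1 (adjusted p = 0.905). None of these 3 lists was called, but with the 3' minus 5' covariate DNA replication was (median -0.25, adjusted p = 0.0211 at the preset correlation). The median of cyclins was 0.00, and -0.12 with the covariate, and their mean was -0.01. The median of histones was -0.10, and 0.12 centred on the hybridisation controls and 0.11 without bioB, and their mean was 0.015. RNR1 at -0.11 ± 0.13, HTB2 at -0.13 ± 0.06 and CLN1 at 0.16 ± 0.11 were not called. Centred on the hybridisation controls RNR1 was at 0.12 and HTB2 at 0.09, and they were not called there either. In total 3319 genes were called between day 10 and day 6, 1571 higher and 1748 lower, and 1595 higher and 343 lower centred on the hybridisation controls, where 1938 were called. Without bioB 1493 were higher and 328 lower. The 3' minus 5' signal of the control genes was 1.65 ± 0.05 on day 6 and 1.28 ± 0.07 on day 10 (SD, n = 3), and with that signal as a covariate 2863 genes were called, of which 2483 had been called in the same direction without it. RNR1 was then called at -0.51, and HTB2 was called at -0.16 without day 10 replicate 2.

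Across the whole stationary interval, from day 2 to day 10, ribosome biogenesis genes rose in 86 of 91 cases and none fell (median 0.82, 0.27 centred on the hybridisation controls and 0.49 with the 3' minus 5' covariate; adjusted p = 1.05e-16; adjusted p = 0.404 with an estimated correlation). RRP14 was at 1.54 ± 0.12 and NSR1 at 1.52 ± 0.15. Amino acid biosynthesis genes rose in 38 of 43 cases and fell in 3 (median 0.55, 0.01 centred on the hybridisation controls and -0.04 without bioB; adjusted p = 8.60e-08; adjusted p = 0.172 with an estimated correlation). HOM3 was at 2.12 ± 0.06 and HIS1 at 1.60 ± 0.08. Trehalose and glycogen genes fell in 17 of 21 cases and rose in 4 (median -0.97, adjusted p = 1.76e-05; adjusted p = 0.404 with an estimated correlation). UGP1 was at -2.55 ± 0.10 and GPH1 at -2.46 ± 0.27. RTN2 was at -2.64 ± 0.15, and the antioxidant genes CTT1 and AHP1 were at -2.24 ± 0.20 and -2.18 ± 0.11. All 7 MATa-specific genes fell (median -3.39, adjusted p = 1.95e-06; adjusted p = 0.292 with an estimated correlation), with BAR1 at -3.73 ± 0.10, AGA2 at -3.64 ± 0.12 and STE2 at -3.39 ± 0.09.

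The highest genes of day 10 against day 2 were ANS1, at least 13.5-fold higher, YMR244W at 3.69 ± 0.15, the sodium-phosphate transporter PHO89 at 3.13 ± 0.15, NCA3 at 3.09 ± 0.11 and ALD5 at 2.64 ± 0.07. The lowest were ZPS1 at -4.69 ± 0.24, HXT3 at -4.44 ± 0.09, MF(ALPHA)1 at -4.17 ± 0.13, AGA1 at -3.83 ± 0.11 and THI13 at -3.79 ± 0.07. In total 3654 genes were called, 1903 higher and 1751 lower, and 271 higher and 3685 lower centred on the hybridisation controls. Without bioB 240 were higher and 3836 lower. With the 3' minus 5' signal as a covariate 2425 genes were called, of which 2235 had been called in the same direction without it.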

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

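The tests of the alpha-specific genes, of silencing, of dividing cells and their criteria, of the bioB control and with the covariate were chosen after the results were seen, while the test against gene length and the splits of the arrays were set before their outcome was known.

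All 7 MATa-specific and 9 of 10 haploid-specific genes rose on day 2, and as many of each list fell from day 2 to day 6. The trend with gene length had a Spearman's rho of 0.235 across genes, which are not independent replicates. With it removed, the median rise of these 17 genes was 1.45 ± 0.32 (standard error), against 1.55 before. This cannot decide on RNA integrity, because the trend did not follow the 3' minus 5' signal. Its rho was 0.216 for day 6 against log phase, while the signal was 0.86 on day 2, 1.25 in log phase and 1.65 on day 6. With that signal as a covariate the list medians were 2.40 (MATa-specific) and 1.27 (haploid-specific), against 2.34 and 1.07 without it. Loss of silencing at the silent mating-type loci in most cells would lower the haploid-specific genes, whose median was 1.07 ± 0.45. The strain was taken to be haploid and of mating type a. Alpha cells in the day 2 cultures would raise all 4 alpha-specific genes, in 1 ratio at every time if their profile were fixed. Of these 3 rose. MF(ALPHA)2 (-0.08 ± 0.06) lay near background, where differences are compressed, so it decides nothing. From day 2 to day 10 MF(ALPHA)1 fell by 4.17 ± 0.13 and SAG1 by 0.95 ± 0.09, while STE3, at 0.10 ± 0.06, was not called. These unlike changes argue against a fixed profile. Alpha cells stay open, since SAG1 and STE3 also had signal above background in log phase (6.60 and 6.47, against 5.82). So does the time point, as an untested biological explanation.

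Ribosome biogenesis and amino acid genes were higher on day 10 than on day 6, while the 3' minus 5' signal was lower. With that signal as a covariate the mean rise was 1.13 ± 0.123 (standard error) for ribosome biogenesis, against 0.847 without it. For amino acid biosynthesis it was 0.754 ± 0.0504, against 0.786. Leaving out each array in turn gave mean rises of 1.05 to 1.18 and 0.732 to 0.808. The slope rests mainly on the day 2 arrays, where the signal had an SD of 0.24, against 0.05 to 0.07 at the other times. Whether it holds on days 6 and 10 was not tested. If it does, the values argue against RNA integrity, as far as this signal measures it, as the whole cause. For each list, cyclin, replication and histone genes were taken that were at least as far above day 6 in log phase. With any share of cells dividing as in log phase, these genes would rise at least as much as the list, if all other cells kept their day 6 profile. For ribosome biogenesis, which rose by 0.843, their median was 0.0647 ± 0.32 (SD of 11 genes). For amino acid biosynthesis, which rose by 0.837, it was -0.00622 ± 0.278 (37 genes), and 0 genes reached the rise of either list. The amino acid list was only 0.28 above day 6 in log phase. On the deposited scale no share of such cells among cells with the day 6 profile could thus raise it by 0.837, so its 37 genes decide nothing there. Centred on the hybridisation controls the list was below log phase on day 10 (median -0.42), and there the 37 genes do bear on it. Cells that divide with another profile, a dividing share masked by a change in the other cells, and the time point itself, remain as untested explanations.

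The bioB control, which is not one of the genes compared, was low against bioC on the log phase arrays. The difference between the other arrays and log phase was 1.31. Compression towards the floor that depends on level alone would let the dimmer bioB change no more than bioC, but from log phase to day 2 bioB changed by 1.17 ± 0.249 (spread between arrays) and bioC by -0.21 ± 0.308. A separate control mixture or hybridisation batch for the log phase arrays cannot be told apart from growth phase, since all 3 log phase arrays and no others would be in it. A hybridisation batch would also enter every comparison of genes and lists with log phase, and its share in them was not tested. No biological explanation was tested, because the control is not yeast RNA.

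Of 3470 probe sets without a gene in the annotation, which the comparisons do not use, 55, 62 and 51 were called with a change of at least 2-fold on days 2, 6 and 10 against log phase, and 41, 45 and 37 of these were higher. At the same limit 1250, 1464 and 1051 of 5449 genes were called, a larger share, and 0 of 1746 probe sets of another yeast species on each day.

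In 1 of 100 splits of the 12 arrays into 4 groups, the real one, 5204 genes were called over the 4 times. The highest other split called 2822, so a random assignment of the arrays to groups can be excluded for that count. Among days 2, 6 and 10, 1 of 100 splits called as many as the real 4631. The highest other called 2175, so a random assignment can be excluded there too. The splits cannot exclude chance differences between cultures, because the labels do not say whether the arrays of a time came from separate cultures. Nor can they exclude a batch that follows time, which would give the same outcome. For each pair of times the 6 arrays make 10 splits, too few for a share under 0.05. In every split but the real one each group mixes both times, which widens the spread within groups, so few calls there were foreseeable. The real counts were 4387, 4505 and 4321 for days 2, 6 and 10 against log phase, 3659 for day 6 against day 2, 3319 for day 10 against day 6 and 3654 for day 10 against day 2, and the highest other split of each called 0.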

How the results depend on the processing

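The spike-in centring without bioB and the covariate were chosen after the data were seen. Of 204 alternative values of the 8 counts of changed genes 194 lay within 1.5 times the count reported. With the 3' minus 5' signal as a covariate, 1636 genes were called for day 6 against day 2 (3659 without it) and 2425 for day 10 against day 2 (3654 without it). Centred on the hybridisation controls, 1938 genes were called for day 10 against day 6, and 1821 without bioB (3319 as deposited); the cause of these changes was not tested. A 2-fold minimum left 1250, 1464 and 1051 genes for days 2, 6 and 10 against log phase, 349 for day 6 against day 2, 280 for day 10 against day 6 and 430 for day 10 against day 2, by its construction. Centred on the hybridisation controls, genes called and changed at least 2-fold numbered 3449 for day 6 and 2797 for day 10 against log phase, 1542 for day 6 against day 2 and 860 for day 10 against day 2; without bioB the numbers were 2521, 1903, 1716 and 968. Camera called 26, 21, 26, 18, 21 and 21 lists with the preset correlation and 0 in each with an estimated one, where 9, 6, 5, 5, 4 and 5 lists had an unadjusted p under 0.05. With the covariate camera called 27, 20, 26, 20, 21 and 24 lists at the preset correlation, but not always the same ones. The median of the sulfur and methionine list for day 10 against day 6 went from 0.51 to -0.03 and its call was lost (camera adjusted p = 0.00394 and 0.793). For day 6 against day 2 the glycolysis, proteasome, cyclin and ergosterol lists lost their call. Ribosome biogenesis gained it (median -0.06 to -0.63, camera adjusted p = 1.94e-10 with the covariate). So did the sulfur and methionine (median 0.11 to 1.12), autophagy, DNA replication, iron and MATalpha-specific lists. Of 3580 alternative values of the 179 named gene differences, 3557 kept their direction and side of the threshold, 12 lost the call, 9 gained it and 2 reversed: TOR1 for day 6 against log phase was -1.04 centred on the hybridisation controls and -0.70 without bioB. TOR1 there lost its call without log phase replicate 2 (0.13) and without day 6 replicate 1 (0.13). Leaving out each array in turn reversed 0 calls, and at most 422 calls were lost (day 10 against day 6 without day 10 replicate 3). The values do not settle whether same-numbered arrays pair. Of 18 such pairs 5 had a correlation of deviations over 0.1 (range -0.29 to 0.393, and -0.357 to 0.36 for other pairs), and 7 of 12 arrays correlated best with their own number. With the replicate block 4370 genes were called for day 2 against log phase and 3626 for day 6 against day 2. Signal over background limits the 188 dim genes.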

Other observations

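The following genes of thiamine metabolism, apart from THI4, THI13 and PDC5, were chosen after their values were seen; they are not a fixed list and were not tested as a group. On day 2 against log phase the transporter-like gene THI73 rose by 4.10 ± 0.10, the thiamine phosphate synthesis gene THI20 by 2.71 ± 0.07 and the regulators THI2 and THI3 by 2.03 ± 0.09 and 0.48 ± 0.07. From day 2 to day 6 THI13 fell by 3.07 ± 0.07 and PDC5, which encodes a thiamine-dependent enzyme, by 3.68 ± 0.14, while THI4 fell by 0.64 ± 0.08 and THI2, at -0.05 ± 0.09, was not called.

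The zinc-responsive gene ZPS1 was at 0.76 ± 0.24 on day 2 against log phase, at -1.45 ± 0.24 on day 6 against day 2 and at -3.24 ± 0.24 on day 10 against day 6. The copper transporter gene CTR3 was at -2.23 ± 0.17, 2.81 ± 0.17 and -2.34 ± 0.17 over the same steps.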
